A study of Homo sapiens with 6 samples.

How the data were processed

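The data were RNA-seq values per gene from 6 libraries of cultured primary AML cells, 3 from vehicle-treated controls and 3 from cells treated with OSU-2S. Groups and library numbers were taken from the sample titles and treatment labels. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the TruSeq stranded mRNA kit, which selects polyadenylated RNA. The submitters' processing notes name CASAVA 1.8.2, HISAT2 2.0.6, the genome build GRCh38.p7, featureCounts from Subread, and DESeq2, the last 3 tools without a version. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. Reads of overlapping or antisense genes may therefore not be separated, and genes with near-identical copies, such as HSPA1A and HSPA1B or the histones, share reads.

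The deposited table holds 1 signal value per gene symbol and library, which is a read count divided by a size factor of that library. This was worked out from the values: all values in each column (100%, tolerance 0.001 of a read) were whole multiples of 1 step. The inverse of that step equalled a median-of-ratios size factor, the kind the authors' tool DESeq2 computes, and ranged from 0.857 to 1.43. Multiplying back implied 28810939 to 46817915 reads per library, while the column totals were 32095203 to 35508617. Deeper libraries give smaller counting error, so low values in control 3 are the most precise. The number of columns not used was 0.

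The test planned before the data were examined assumed raw counts and edgeR, which was not used because the table holds normalised values. A count model such as edgeR or DESeq2 was not run on the recovered reads either. Limma-voom on these reads, scaled by the size factors, was added as an alternative. Genes with a value of at least 10 in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3 (2-group model, no covariate, trended and robust variance) on log2(value + 1). A fold change is therefore on the log2(value + 1) scale, which understates the change of low genes. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05, and every adjusted p of a gene comes from limma. Gene lists were tested with camera from limma, 2-sided, with a preset correlation of 0.01 and adjustment over the 34 lists with at least 3 tested members. Each list was also tested with an estimated correlation and with fry. With an estimated correlation, camera takes its degrees of freedom from the libraries, and with a preset one from the many genes. The test with an estimated correlation is therefore stricter for small p-values at any correlation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and figures. Nothing in the labels says whether the 3 libraries of a group came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

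The gene lists, the naming rule, the groups and the first set of alternatives were fixed before the data were examined. The lists were MYC network, MYC-driven ribosome biogenesis, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors, p53 targets, PP2A subunits and inhibitors, monocyte and macrophage differentiation, secondary granule and mature neutrophil, primary granule, stem and progenitor, myeloid transcription factors, sphingolipid metabolism and S1P receptors, and cholesterol biosynthesis and uptake. Further lists were LXR targets, lysosome, autophagy, ATF4 response, endoplasmic reticulum chaperones, NRF2 targets, heat shock response, BCL2 family, NF-kB and inflammatory cytokines, interferon-stimulated genes, immediate early genes, MHC class II, hypoxia and glycolysis, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, and replication-dependent histones. Markers of T cells, NK cells, B and plasma cells, erythroid cells, megakaryocytes and platelets, mast cells with basophils and eosinophils, dendritic cells, and stromal and endothelial cells stood for other cells in the culture. Some genes are members of several lists, such as EGR2, ATF3, CDKN1A, SLC7A11 and BBC3.

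The naming rule took MYC and CDKN1A whatever their p, and the 6 genes with the largest positive and the 6 with the largest negative log2 change among those that passed. These 12 also needed a mean log2 CPM of at least 1, a symbol that is not a clone name, and no overlap between groups. From each list it took up to 4 members: of those that passed, the 2 largest in each direction where calls went both ways and the 3 largest where they went 1 way, or the 2 smallest p where none passed. For lists of other cell types it took the 2 members with the highest mean CPM, of which 1 gene is not reported here. Where a list had 5 or fewer calls in a direction, the remaining members were named after their values were seen: SESN2, CD36, CPXM1, SMPD1, SPNS2, LPCAT3, MYLIP, HERPUD1, SYVN1, PDIA4, BCL2L11, KDM3A, SLC2A3, TPSAB1 and VWF. CDT1, SREBF2, HSPA1B, PDGFRB, MT-ND6 and the genes in the closing observations were also chosen after their values were seen. For all 130 named genes that passed, the groups did not overlap. XIST and Y-linked genes were left out because the cells come from human donors.

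Older symbols in the table were matched to the listed ones through a table of RefSeq synonyms, for 8 list members. Positions came from GENCODE v29 on GRCh38, in which 35157 (63.0%) of the symbols were found by name. GC content and transcript length were available for 13894 tested genes (85.7%). The test was checked on simulated data for the OSU-2S comparison with 16013 genes tested: 31% of 100 genes changed 1.5-fold and 91% of 100 genes changed 3-fold were recovered, 1.50% of calls were false, and 1% of unchanged lists reached p under 0.05. Limma-voom on simulated reads of the same 16013 genes recovered 33% and 91%. These rates hold for the simulated genes only. In the measured data the estimated correlation within a list reached 0.883, for cytosolic ribosomal proteins, against the preset 0.01. The simulated false rates therefore do not measure the error of gene calls or of camera in the measured data. The GC correction was checked on 13768 simulated genes, where it lowered the rank correlation of deviations with GC from 0.714 to 0.0074 and kept 89.2% of 93 genes changed 3-fold.

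Alternatives fixed before the data were examined were total scaling, no filter, a filter at a CPM of 1 in 3 libraries, limma-voom, a threshold of 0.01, an absolute log2 change of at least 1, leaving out each library in turn, the estimated correlation and fry. Chosen after seeing the data were pseudocounts of 0.5 and 10, quantile normalisation, restriction to genes with a GC value, a correction of each library for GC and length, limma-voom on the recovered reads, and leaving out control 2 and OSU-2S 4 or giving them a covariate.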

Results

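RNA was measured in primary acute myeloid leukaemia (AML) cells kept in culture. The labels name a serum-free stem cell medium or RPMI with serum, and the cytokines IL3, GM-CSF and SCF as supplements, without saying which medium these samples had. AML is a blood cancer in which immature myeloid cells build up. Of the 6 libraries of polyadenylated RNA, 3 came from vehicle-treated control cells (control 1 to 3) and 3 from cells given OSU-2S (OSU-2S 4 to 6). OSU-2S is a derivative of fingolimod (FTY720) that is described as an activator of protein phosphatase 2A (PP2A) without the immunosuppressive action of its parent compound. The dose and the length of treatment are not given in the sources used here. The step size of the deposited values implied 28810939, 29588548 and 46817915 reads assigned to genes in control 1, 2 and 3, and 35333921, 32017561 and 32284902 reads in OSU-2S 4, 5 and 6. Between 22750 and 24238 of 55765 gene symbols had a value above 0 per library. Across genes, log2 values correlated at r = 0.986 to 0.995 within groups and at r = 0.967 to 0.980 between them. No pair of libraries was as alike as sampling noise allows, with chi-square per degree of freedom between 7.94 and 57.5 within groups.

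The comparison of OSU-2S with control cells addressed the subjects named in the title of the series, namely PP2A, c-Myc, p21, differentiation and the cell cycle. All 24 tested genes on a list for cholesterol biosynthesis and uptake rose in OSU-2S, with a median log2 change of 2.70. Among genes of the G1/S transition and DNA replication, 34 of 35 fell, with a median of -0.96. MYC fell by 0.32 on the log2 scale (SE 0.10, n = 3 per group), and CDKN1A, which encodes p21, rose by 0.52 (SE 0.12). Both calls ended in some of the fits that left out 1 library. Genes of the ATF4 stress response, NF-kB targets and interferon-stimulated genes were mostly higher, while ribosome biogenesis and heat shock genes were mostly lower. The count of lower ribosome biogenesis genes ran from 10 to 31 of 36 in fits without 1 library. Of 16217 genes tested with limma, 1680 were higher and 1519 lower at a Benjamini-Hochberg adjusted p under 0.05, which is 19.7% of the genes tested. An unadjusted p under 0.05 was reached by 2701 genes in the higher and 2767 in the lower direction. The groups did not overlap for 3043 genes that were higher and 3052 that were lower, together 37.6% of the genes, where chance gives 10%. An absolute log2 change of at least 1 was reached by 726 of the higher and 242 of the lower genes. Of the 34 gene lists tested with camera, 15 passed an adjusted p of 0.05 with the preset correlation, and of these only the cholesterol list also passed with an estimated correlation. The test with an estimated correlation takes its degrees of freedom from the 6 libraries and is stricter at any correlation. Failing it does not by itself show that the genes of a list are correlated. The first principal component held 59.5% of the variance and separated the groups, and the second held 22.0% and separated control 2 and OSU-2S 4 from the other 4 libraries.

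The counts of genes were lower in fits without some of the libraries. Without control 1, control 3, OSU-2S 5 or OSU-2S 6 the numbers of higher and lower genes were 1163 and 791, 957 and 569, 954 and 639, and 1130 and 874. Leaving out control 2 and OSU-2S 4 together, a choice made after seeing the data, gave 3061 higher and 3674 lower genes, among them 1647 of the 1680 and 1505 of the 1519. Control 2 also stood apart in its stromal transcripts. COL1A1 and COL1A2, the chains of type I collagen, had normalised read counts of 1168 and 1025 in control 2 and of at most 64.5 and 39.2 in any other library.

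Levels below are mean normalised read counts ± SD with n = 3 libraries per group, and log2 changes are OSU-2S minus control ± SE from limma. KLF2, a transcription factor that restrains inflammatory gene expression, was the gene with the largest increase among those that met the naming rule, from 14.8 ± 2.53 to 798 ± 99.6 (log2 5.67 ± 0.19, adjusted p = 3.24e-07; chromosome 19, 16324817 to 16327874). C6orf223 rose from 33.6 ± 0.181 to 945 ± 191 (log2 4.75 ± 0.17; chromosome 6, 44000580 to 44005958). HMGCS1, the cytosolic HMG-CoA synthase of the mevalonate pathway, rose from 940.1 ± 158 to 19746 ± 4042 (log2 4.38 ± 0.18; chromosome 5, 43289395 to 43313512). The organic anion transporter gene SLCO4C1 rose from 47.0 ± 6.83 to 916 ± 229.7 (log2 4.23 ± 0.21; chromosome 5, 102233986 to 102296549). LSS, the lanosterol synthase, rose from 1458 ± 138 to 24665 ± 1865 (log2 4.08 ± 0.11, chromosome 21, 46188141 to 46228824), and the serotonin receptor gene HTR2B from 18.4 ± 3.92 to 324 ± 89.9 (log2 4.05 ± 0.24, chromosome 2, 231108230 to 231125118). In the other direction, UNG, the uracil DNA glycosylase, fell from 2031 ± 143 to 390.4 ± 45.9 (log2 -2.38 ± 0.13, adjusted p = 4.03e-06, chromosome 12, 109097574 to 109110992). CCNE2, which encodes cyclin E2, fell from 509 ± 146 to 97.9 ± 29.2 (log2 -2.36 ± 0.26, chromosome 8, 94879770 to 94896678). ABCA1, a cholesterol efflux transporter, fell from 258 ± 105 to 49.6 ± 17.8 (log2 -2.34 ± 0.35, chromosome 9, 104781002 to 104928237). C1orf106, VIT and CACNA2D3 followed with log2 changes of -1.82 ± 0.19, -1.81 ± 0.18 and -1.79 ± 0.21 (chromosome 1, 200891048 to 200915735, chromosome 2, 36696690 to 36814792, and chromosome 3, 54122547 to 55074557). Adjusted p was at most 0.00185 for these 12 genes. As the naming rule required, all 3 OSU-2S libraries lay on the same side of all 3 controls for each of them. Positions are gene bodies in the GENCODE v29 annotation of GRCh38.

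MYC (chromosome 8, 127735434 to 127741434) fell from 15369 ± 543 to 12332 ± 573 normalised reads (log2 -0.32 ± 0.10, adjusted p = 0.0459), and CDKN1A (chromosome 6, 36676460 to 36687339) rose from 10361 ± 1245 to 14791 ± 1178 (log2 0.52 ± 0.12, adjusted p = 0.0148). Both differences separated all 3 OSU-2S libraries from all 3 controls. Of 11 tested members of the MYC network, MXD1, which encodes a MAX partner that opposes MYC, rose (log2 0.69 ± 0.17), MYC fell and 9 did not pass, with 1 higher and 1 lower adjusted over the list alone and no call for the list (adjusted p = 0.445). Ribosome biogenesis genes that MYC is known to drive fell in 26 of 36 cases, none rose, and 0 higher and 30 lower adjusted over the list alone. PUS7 (-0.996 ± 0.17), NME1 (-0.80 ± 0.19) and MYBBP1A (-0.79 ± 0.12) fell most in this list, whose median was -0.53 (camera adjusted p = 1.99e-12, and adjusted p = 0.20 with an estimated correlation). Among 8 CDK inhibitor genes, CDKN1C (1.49 ± 0.16), CDKN2B (0.98 ± 0.19), CDKN2D (0.83 ± 0.14) and CDKN1A rose, 4 did not pass, and 4 higher and 0 lower adjusted over the list alone. That list passed with the preset correlation (adjusted p = 0.0394) and not with an estimated one (adjusted p = 0.215 with an estimated correlation), without control 2 (adjusted p = 0.0509) or after correction for GC content and length (adjusted p = 0.0515). Of 26 p53 target genes, 5 rose, 6 fell and 15 did not pass, with 6 higher and 10 lower adjusted over the list alone. The risers were GDF15 (2.82 ± 0.40), BTG2 (1.15 ± 0.14), BBC3 (1.12 ± 0.13), SESN2 (0.75 ± 0.14) and CDKN1A, and TRIAP1 (-0.76 ± 0.14) and FDXR (-0.72 ± 0.16) fell most. GDF15 was low, at means of 2.10 in control and 20.8 in OSU-2S. The p53 list had a median of -0.24, a mean of 0.01 and a test direction of lower, and it did not pass (adjusted p = 0.567). Its median was -0.15 without control 3.

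Several of these calls ended when 1 library was left out. Among all named genes, 132 such fits ended a call, and in 130 of them the log2 change lay within 1 SE of that from all 6 libraries. That bound was nearly fixed in advance, because with 3 libraries per group leaving out 1 can hardly move the change further. The call of the MYC log2 fold change ended without control 1, control 3, OSU-2S 5 or OSU-2S 6 (adjusted p = 0.117 to 0.184), at -0.34 to -0.28, and with no filter on low values (adjusted p = 0.0831). That of CDKN1A ended without control 1, control 3 or OSU-2S 5 (adjusted p = 0.0658 to 0.0813), at log2 changes of 0.46 to 0.48. Those of MXD1 and NME1 ended without control 3, OSU-2S 5 or OSU-2S 6 (adjusted p = 0.0510 to 0.0983), and that of FDXR without OSU-2S 5 (adjusted p = 0.0532). Ribosome biogenesis genes lower in OSU-2S numbered 15 without control 1, 11 without control 3, 10 without OSU-2S 5 and 14 without OSU-2S 6. For p53 target genes the lower count was 3 without control 1 or control 3 and 2 without OSU-2S 5.

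**Figure D1:**
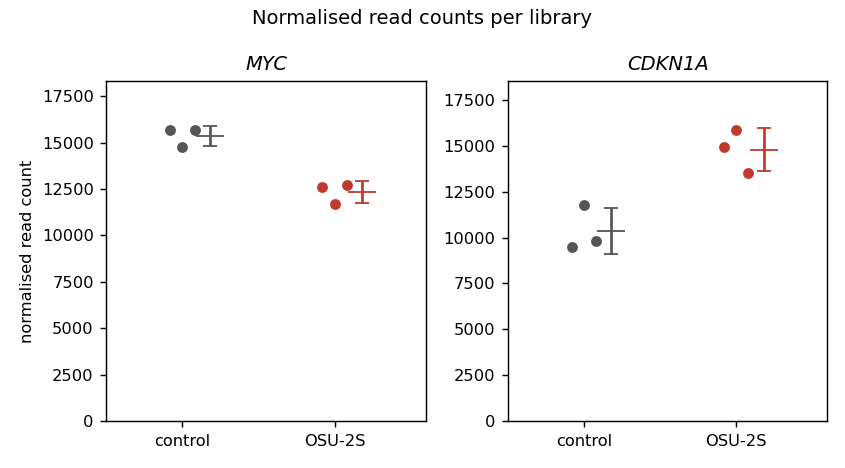
Normalised read counts of MYC and CDKN1A (vertical axes, starting at 0) in the 3 control and 3 OSU-2S libraries (horizontal axis). Points are libraries, and dashes with bars are the group mean ± SD: MYC had 15369 ± 543 in control and 12332 ± 573 in OSU-2S, and CDKN1A 10361 ± 1245 and 14791 ± 1178.

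Genes of the G1/S transition and DNA replication fell together: 34 of 35 were lower, 0 were higher, and 0 higher and 34 lower adjusted over the list alone. CCNE2 (log2 -2.36 ± 0.26), the chromatin assembly factor gene CHAF1B (-1.60 ± 0.14) and MCM4 (-1.50 ± 0.11), a subunit of the replicative helicase, fell most. The member that did not pass was CDT1, at 0.04 ± 0.13. The list passed with the preset correlation (camera adjusted p = 9.85e-25) and not with an estimated one (adjusted p = 0.0608 with an estimated correlation). Genes of G2/M and mitosis moved less, with a median of -0.22. Of 34 members, CDK1 (-0.62 ± 0.16), BUB1B (-0.50 ± 0.14) and NUSAP1 (-0.44 ± 0.13) fell, 31 did not pass, and 0 higher and 0 lower adjusted over the list alone. The G2/M list passed as a set (adjusted p = 0.000812, and adjusted p = 0.282 with an estimated correlation). Its calls depended on the libraries used: 0 members were lower without control 1, control 3 or OSU-2S 5, 8 were lower without control 2, 5 without OSU-2S 4, and 23 without both control 2 and OSU-2S 4. CDK1 lost its call without control 1, control 3 or OSU-2S 5 (adjusted p = 0.0578 to 0.103), BUB1B without control 1, control 3, OSU-2S 4 or OSU-2S 5 (adjusted p = 0.0556 to 0.157), and NUSAP1 without control 1, control 3, OSU-2S 4, OSU-2S 5 or OSU-2S 6 (adjusted p = 0.0507 to 0.169). Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, went the other way in this polyadenylated RNA. Of 39 tested, 13 rose, 0 fell and 26 did not pass, with 17 higher and 0 lower adjusted over the list alone (median 0.68, adjusted p = 4.42e-07, and adjusted p = 0.150 with an estimated correlation). HIST2H2BE (2.04 ± 0.15), HIST1H4C (1.48 ± 0.34) and HIST1H2AC (1.24 ± 0.20) rose most, although near-identical histone copies share reads and their values are uncertain. The call of HIST1H4C ended without control 3 or OSU-2S 6 (adjusted p = 0.0575 to 0.0636), and the count of higher histone genes was 23 without control 2 and OSU-2S 4.

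**Figure D2:**
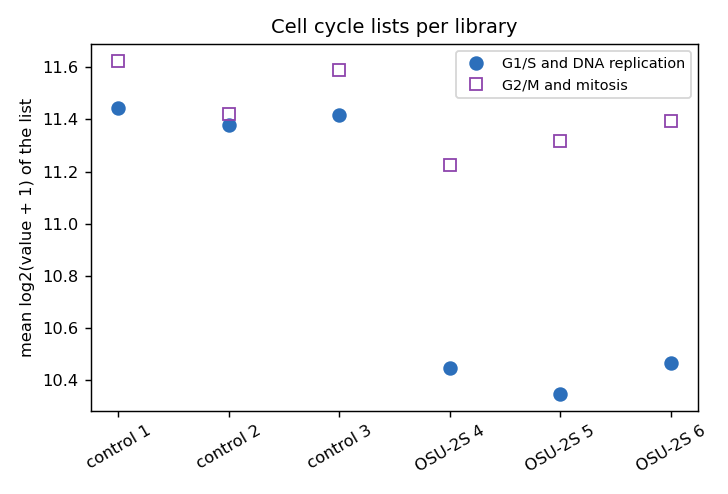
Mean log2(value + 1) over the tested members of the G1/S list (circles) and the G2/M list (open squares) on the vertical axis, for each library on the horizontal axis. The G1/S means were 11.38 to 11.44 in the control and 10.35 to 10.47 in the OSU-2S libraries, and the G2/M means were 11.42 to 11.63 and 11.22 to 11.40.

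Markers of myeloid maturation moved in both directions. Of 15 tested monocyte and macrophage genes (25 listed), MS4A7 (log2 1.20 ± 0.22), the integrin gene ITGAX (1.05 ± 0.14) and the scavenger receptor gene CD36 (0.76 ± 0.16) rose. In the same list 7 fell, among them lysozyme (LYZ, -1.67 ± 0.13) and S100A9 (-1.23 ± 0.37), and 5 did not pass, with 3 higher and 7 lower adjusted over the list alone and no call for the list (adjusted p = 0.174). S100A9 lay near the filter on low values, at means of 15.8 in control and 6.37 in OSU-2S, while LYZ was at 28859 and 8998. Among secondary granule and mature neutrophil genes, FPR2 (-1.92 ± 0.46) and CXCR2 (-1.02 ± 0.13) fell, 5 of 7 tested (24 listed) did not pass, and 1 higher and 2 lower adjusted over the list alone (adjusted p = 0.315). FPR2 was also near the filter, at means of 16.5 in control and 3.68 in OSU-2S. Primary granule genes, a mark of promyelocytes, fell in 7 of 12 cases and rose in 0, with 1 higher and 7 lower adjusted over the list alone. The eosinophil ribonuclease genes RNASE2 (-1.41 ± 0.14) and RNASE3 (-1.22 ± 0.15) and MS4A3 (-1.17 ± 0.11) fell most in that list, which passed with the preset correlation (adjusted p = 0.00171, and adjusted p = 0.423 with an estimated correlation). Of 17 tested stem and progenitor genes, MN1 (1.09 ± 0.23) rose, KIT (-0.96 ± 0.21), LAPTM4B (-0.90 ± 0.17) and CPXM1 (-0.70 ± 0.21) fell, and 13 did not pass, with 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.695). Myeloid transcription factor genes rose in 6 of 16 cases, led by EGR2 (3.39 ± 0.47) and CEBPB (0.93 ± 0.13), while VDR (-0.41 ± 0.11) and IRF8 (-0.34 ± 0.10) fell and 8 did not pass. EGR2 was low, at means of 2.72 in control and 39.2 in OSU-2S. Adjusted over the list alone the counts were 6 higher and 2 lower, and the list had no call (adjusted p = 0.153). HLA-DQB1 (-0.75 ± 0.16) and HLA-DRA (-0.49 ± 0.13), which encode MHC class II chains, fell, while 6 of 8 tested genes of that list did not pass, with 0 higher and 3 lower adjusted over the list alone (adjusted p = 0.145).

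Among the maturation genes, the calls of VDR, IRF8, FPR2 and HLA-DRA ended without control 1, control 3, OSU-2S 5 or OSU-2S 6 (adjusted p = 0.0541 to 0.139). KIT and HLA-DQB1 lost theirs without control 3 (adjusted p = 0.0575 to 0.0647), CD36 without OSU-2S 5 (adjusted p = 0.0515), CPXM1 without control 2, control 3, OSU-2S 5 or OSU-2S 6 (adjusted p = 0.0945 to 0.139), and S100A9 without control 1, control 2, control 3, OSU-2S 4 or OSU-2S 5 (adjusted p = 0.0589 to 0.140). Primary granule genes lower in OSU-2S numbered 4 without control 3, OSU-2S 5 or OSU-2S 6, and the lower stem and progenitor count was 1 without control 3. In the neutrophil list, 1 gene was higher without control 2.

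All 24 tested genes on the list for cholesterol biosynthesis and uptake rose, with all 6 libraries and without any 1 of them, and 24 higher and 0 lower adjusted over the list alone. HMGCS1 (log2 4.38 ± 0.18), LSS (4.08 ± 0.11) and DHCR7 (3.96 ± 0.14), which encodes the last enzyme of the Kandutsch-Russell route, rose most, and the smallest increase was that of SREBF2 (1.49 ± 0.12). This list passed with the preset correlation (camera adjusted p = 1.09e-36) and with an estimated one (adjusted p = 0.0242 with an estimated correlation). PMVK, a mevalonate pathway gene that the list leaves out and that was chosen after its value was seen, did not pass (-0.26 ± 0.14, adjusted p = 0.236). Genes on the list of targets of the sterol-sensing receptor LXR split, and which factor drove each of them was not tested. SCD (3.47 ± 0.11), SREBF1 (0.95 ± 0.11) and LPCAT3 (0.43 ± 0.10), which act in fatty acid and phospholipid synthesis or its control, rose. The efflux transporter genes ABCA1 (-2.34 ± 0.35) and ABCG1 (-1.82 ± 0.47) and MYLIP (-0.93 ± 0.14), which encodes a ligase that degrades the LDL receptor, fell. ABCG1 lay near the filter on low values, at means of 12.9 in control and 3.35 in OSU-2S. The other 5 of 11 LXR target genes did not pass, with 4 higher and 3 lower adjusted over the list alone (list adjusted p = 0.269). In sphingolipid metabolism (fingolimod is a sphingosine analogue), the receptor gene S1PR2 (1.72 ± 0.32), the acid ceramidase gene ASAH1 (1.07 ± 0.16), SMPD1 (0.52 ± 0.14) and SPNS2 (0.52 ± 0.13) rose. CERK (-0.45 ± 0.11) and DEGS1 (-0.37 ± 0.12) fell, and 19 of 25 did not pass, with 4 higher and 2 lower adjusted over the list alone (adjusted p = 0.275). Of 27 tested genes for PP2A subunits and inhibitors, the regulatory subunit gene PPP2R5B (0.85 ± 0.13) rose, the scaffold gene PPP2R1B (-0.79 ± 0.16) and the inhibitor gene ANP32A (-0.36 ± 0.11) fell, and 24 did not pass. Adjusted over the list alone, 1 PP2A gene was higher and 1 lower, and the list had no call (adjusted p = 0.567).

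Lysosomal genes rose in 10 of 30 cases and fell in 0, with 12 higher and 0 lower adjusted over the list alone. SGSH (2.59 ± 0.18), the sialidase gene NEU1 (1.53 ± 0.13) and NPC1 (1.35 ± 0.16), which moves cholesterol out of lysosomes, rose most (list median 0.11, adjusted p = 0.000951, and adjusted p = 0.305 with an estimated correlation). Of 17 autophagy genes, 6 rose, 0 fell and 11 did not pass, with 8 higher and 0 lower adjusted over the list alone. WIPI1 (3.22 ± 0.15) and the receptor genes OPTN (1.89 ± 0.14) and SQSTM1 (1.65 ± 0.10) led that list (median 0.12, adjusted p = 0.000290, and adjusted p = 0.113 with an estimated correlation). Among lipid and PP2A genes, the calls of LPCAT3, SMPD1 and SPNS2 ended without control 1, control 3, OSU-2S 5 or OSU-2S 6 (adjusted p = 0.0583 to 0.112). ABCG1 lost its call without control 1, control 2, control 3 or OSU-2S 5 (adjusted p = 0.0511 to 0.0792), CERK without control 3, OSU-2S 5 or OSU-2S 6 (adjusted p = 0.0675 to 0.105), DEGS1 without control 1, control 3, OSU-2S 4, OSU-2S 5 or OSU-2S 6 (adjusted p = 0.0710 to 0.208), PPP2R1B without control 3 (adjusted p = 0.0503) and ANP32A without control 1, control 2, control 3, OSU-2S 5 or OSU-2S 6 (adjusted p = 0.0617 to 0.159). Lower PP2A genes numbered 4 without control 2 and 9 without both control 2 and OSU-2S 4, and 1 lysosomal gene was lower without OSU-2S 4. The lysosome median was 0.17 without control 2 and 0.07 without control 3, and the autophagy median 0.19 without control 1 and 0.21 without OSU-2S 4.

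**Figure D3:**
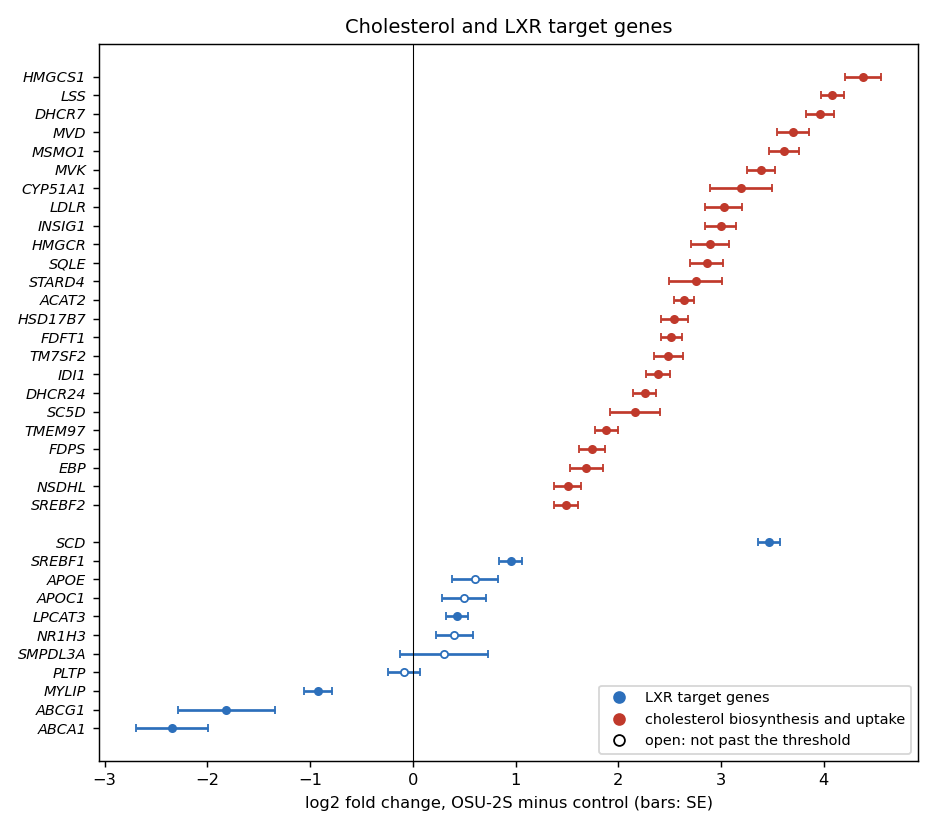
Log2 fold change (OSU-2S minus control, horizontal axis) with its SE for the 24 tested cholesterol genes (red) and the 11 tested LXR target genes (blue), 1 gene per line. Every gene of the cholesterol list lies above 0, from 1.49 for SREBF2 to 4.38 for HMGCS1, while LXR targets run from -2.34 for ABCA1 to 3.47 for SCD, and open symbols did not pass the test.

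Genes of the ATF4 integrated stress response rose in 16 of 23 cases, fell in 0 and did not pass in 7, with 16 higher and 0 lower adjusted over the list alone. NUPR1 (log2 3.09 ± 0.35), ATF3 (2.94 ± 0.15) and TRIB3 (2.88 ± 0.16) rose most (list median 1.02, adjusted p = 3.94e-14, and adjusted p = 0.131 with an estimated correlation). Chaperone and quality-control genes of the endoplasmic reticulum moved both ways. EDEM1 (0.74 ± 0.16), XBP1 (0.72 ± 0.10), HERPUD1 (0.66 ± 0.11) and SYVN1 (0.52 ± 0.11) rose, SDF2L1 (-0.72 ± 0.16), PDIA6 (-0.34 ± 0.10) and PDIA4 (-0.32 ± 0.10) fell, and 11 of 18 did not pass, with 5 higher and 4 lower adjusted over the list alone. The endoplasmic reticulum list had a median of -0.05, a mean of 0.08 and a test direction of higher, with no call (adjusted p = 0.714). That median turned to 0.04 without OSU-2S 5 and was -0.07 to -0.01 without any other library. Targets of the oxidative stress factor NRF2 rose in 9 of 20 cases, led by the cystine transporter gene SLC7A11 (2.22 ± 0.22) and the malic enzyme gene ME1 (2.21 ± 0.22). ABCC1 (-0.47 ± 0.11) fell, 10 did not pass, and 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.00445, and adjusted p = 0.20 with an estimated correlation). Heat shock genes fell in 11 of 16 cases and rose in 0, with 5 not past the threshold and 0 higher and 12 lower adjusted over the list alone. HSPA1A (-1.39 ± 0.21), HSPA4L (-1.24 ± 0.20) and HSPE1 (-0.98 ± 0.15) fell most (list adjusted p = 3.33e-06, and adjusted p = 0.282 with an estimated correlation). HSPA1A shares reads with its near-identical copy HSPA1B (-0.58 ± 0.21), so the split between them is uncertain. In the BCL2 family, BCL2A1 (1.79 ± 0.43), which blocks apoptosis, and BBC3 (1.12 ± 0.13), BMF (0.92 ± 0.13) and BCL2L11 (0.65 ± 0.17), which promote it, rose. The other 10 of 14 BCL2 family genes did not pass, with 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.315). Among hypoxia and glycolysis genes, PFKFB4 (1.87 ± 0.11), VEGFA (1.30 ± 0.14), SLC2A3 (1.09 ± 0.13) and KDM3A (0.48 ± 0.13) rose, LDHA (-0.77 ± 0.12) and PGK1 (-0.66 ± 0.10) fell, and 11 of 17 did not pass, with 4 higher and 2 lower adjusted over the list alone. Their median was -0.03, their mean 0.19 and the test direction higher, with no call (adjusted p = 0.567). That median turned to 0.04 without OSU-2S 4 and was -0.08 to -0.02 without any other library.

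Of the stress genes, SDF2L1 and BCL2A1 lost their calls without OSU-2S 5 (adjusted p = 0.0690 to 0.0723), PDIA6 and BCL2L11 without control 1, control 3, OSU-2S 5 or OSU-2S 6 (adjusted p = 0.0600 to 0.185), and PDIA4 and KDM3A without control 1, control 2, control 3, OSU-2S 5 or OSU-2S 6 (adjusted p = 0.0561 to 0.172). SYVN1 lost its call without control 3 or OSU-2S 5 (adjusted p = 0.0543 to 0.0686) and ABCC1 without control 3, OSU-2S 5 or OSU-2S 6 (adjusted p = 0.0505 to 0.107). Lower endoplasmic reticulum genes numbered 1 without control 1, control 3 or OSU-2S 6, 0 without OSU-2S 5 and 5 without OSU-2S 4, and 2 BCL2 family genes were higher without OSU-2S 5. The lower NRF2 count was 2 without OSU-2S 4.

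None of the 3 lists of inflammatory and early response genes passed with an estimated correlation, although each did with the preset one. Of 16 tested NF-kB and cytokine genes (22 listed), 11 rose, 0 fell and 5 did not pass, with 11 higher and 1 lower adjusted over the list alone. The chemokine gene CCL3 (log2 3.38 ± 0.23) and BIRC3 (3.35 ± 0.23), an inhibitor of apoptosis, rose most next to CCL4 (list median 1.12, adjusted p = 1.09e-08, and adjusted p = 0.131 with an estimated correlation). CCL4 had 3 implied reads over the 3 controls and 55 over the OSU-2S libraries, a ratio of rates of 19.4 (95% exact Poisson interval 6.29 to 96.8, counting error only). Interferon-stimulated genes rose in 14 of 22 cases and fell in 0, with 8 not past the threshold and 18 higher and 0 lower adjusted over the list alone. IFIT3 (3.01 ± 0.18), IFIT1 (2.85 ± 0.28) and IFIT2 (2.66 ± 0.20) led them (list median 0.91, adjusted p = 4.35e-12, and adjusted p = 0.0685 with an estimated correlation). Immediate early genes rose in 12 of 19 cases, with EGR2 (3.39 ± 0.47) among the highest, while DUSP6 (-1.23 ± 0.18), which dampens ERK signalling, fell and 6 did not pass. Adjusted over the list alone, 12 were higher and 2 lower (list median 0.69, adjusted p = 3.76e-07, and adjusted p = 0.150 with an estimated correlation). NR4A3 had 3 implied reads over the controls and 64 over the OSU-2S libraries, a ratio of 22.5 (95% interval 7.37 to 112). The lower immediate early count was 2 without OSU-2S 4.

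**Figure D4:**
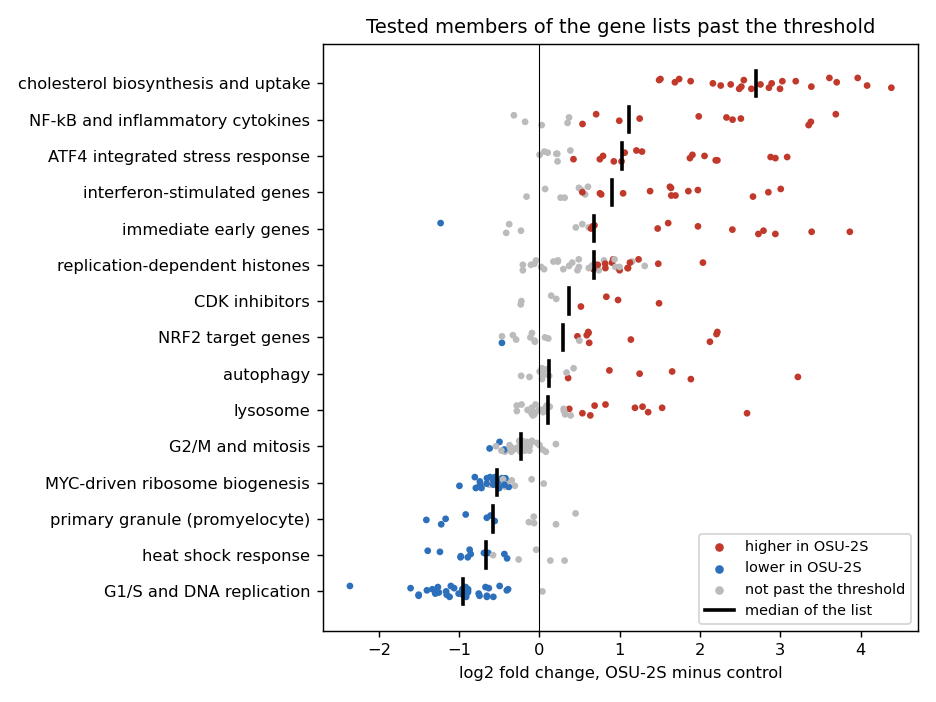
Log2 fold change (OSU-2S minus control, horizontal axis) of every tested member of the 15 gene lists past the threshold with the preset correlation, 1 list per line, with black bars at the list medians. Medians run from -0.96 for the G1/S list to 2.70 for the cholesterol list, and point colours give genes that were higher, lower or not past the threshold.

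Markers of other cell types that a culture of primary AML cells could hold were mostly below the filter on low values. Of 4 tested T cell genes, TRAC rose from 10.8 to 45.2 normalised reads (log2 1.95 ± 0.29), IL7R was at 0.01 ± 0.14, and 3 did not pass, with 1 higher and 0 lower adjusted over the list alone. The T cell median was -0.04, the mean 0.27 and the test direction higher, with no call (adjusted p = 0.686). The median was 0.03 without control 1 and -0.08 to -0.03 without any other library. NKG7, the single NK cell gene tested, was at 0.37 ± 0.15 and did not pass over all genes, with 1 higher adjusted over the list alone, and GNLY was not tested at means of 3.02 and 4.69. Of 6 B and plasma cell genes, BANK1 fell (-1.15 ± 0.27) and 5 did not pass, with 0 higher and 1 lower adjusted over the list alone (adjusted p = 0.695). KLF1, the single erythroid gene tested, was at 0.46 ± 0.25 and did not pass, also adjusted over the list alone, and HBA2 was not tested at means of 0.618 and 2.68. GP9, a platelet gene, fell (-1.14 ± 0.28) and ITGA2B was at -0.41 ± 0.17, with 2 lower adjusted over the list alone. Among 5 mast cell, basophil and eosinophil genes, FCER1A fell (-1.63 ± 0.21), TPSB2 (1.14 ± 0.26) and its near-identical copy TPSAB1 (1.53 ± 0.33) rose, and 2 did not pass, with 2 higher and 1 lower adjusted over the list alone. Their median was -0.24, their mean 0.09 and the test direction higher, with no call (adjusted p = 0.886). Without OSU-2S 6 the median was 0.04, and without any other library -0.32 to -0.10. CLEC10A, a dendritic cell gene, fell (-0.62 ± 0.17) and CCR7 was at 0.46 ± 0.27, with 1 lower adjusted over the list alone. Of 4 stromal and endothelial genes, VWF rose from 14.4 to 82.7 (2.43 ± 0.23), while COL1A1 (-1.10 ± 1.79), COL1A2 (-1.45 ± 1.89) and PDGFRB (0.03 ± 0.42) did not pass, with 1 higher adjusted over the list alone. The stromal median was -0.54, the mean -0.02 and the test direction higher, with no call (adjusted p = 0.533). The negative median came with control 2: it was 0.95 without that library and -1.18 to -0.12 without any other.

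Calls in these marker lists ended in 4 cases when 1 library was left out. BANK1 lost its call without control 1, control 3 or OSU-2S 6 (adjusted p = 0.0549 to 0.0677), GP9 without control 2, control 3 or OSU-2S 5 (adjusted p = 0.0559 to 0.0702), TPSB2 without control 3 (adjusted p = 0.0561) and CLEC10A without control 1, control 2, control 3, OSU-2S 5 or OSU-2S 6 (adjusted p = 0.0580 to 0.120). The log2 changes in those fits were -1.19 to -0.93 for BANK1, -1.17 to -0.86 for GP9, 1.12 for TPSB2 and -0.65 to -0.51 for CLEC10A. Mitochondrially encoded mRNAs, which made up 0.0496% to 0.0707% of the values per library, gave 0 calls among 13 genes, also adjusted over the list alone, while MT-ND5, MT-CO3 and MT-ND6 reached an unadjusted p under 0.05 in limma and 0 genes were called by limma-voom. MT-ND5 was at -0.55 ± 0.21 and MT-CO3 at -0.40 ± 0.16 (list adjusted p = 0.0599, and adjusted p = 0.437 with an estimated correlation). With the preset correlation of 0.01, where the estimate over all 6 libraries was 0.192, the mitochondrial list passed without control 2, control 3 or OSU-2S 5 (adjusted p = 0.0404, 0.0309 and 0.0245), MT-CO3 was called without control 2 (adjusted p = 0.0234) and MT-ND5 without OSU-2S 5 (adjusted p = 0.0338). Among 78 cytosolic ribosomal protein genes, RPS27L (-0.50 ± 0.13) and RPL7L1 (-0.44 ± 0.11), both paralogues of core subunit genes, fell and 76 did not pass, with 0 higher and 0 lower adjusted over the list alone. Their median was 0.07 and the list had no call (adjusted p = 0.565, and adjusted p = 0.906 with an estimated correlation). The estimated correlation of this list was 0.883, so calls at the preset 0.01 are too liberal for it. At that preset its direction followed single libraries, being higher without control 2 or OSU-2S 5 (adjusted p = 0.0367 and 0.00516) and lower without OSU-2S 4 (adjusted p = 0.00728). RPS27L lost its call without control 1, control 2, control 3, OSU-2S 5 or OSU-2S 6 (adjusted p = 0.0501 to 0.0944) and RPL7L1 without control 1, control 3 or OSU-2S 5 (adjusted p = 0.0778 to 0.0925). Ribosomal protein genes with a lower call numbered 5 without OSU-2S 4 and 7 without control 2 and OSU-2S 4.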

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

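The pseudocounts, quantile normalisation, the GC restriction and correction, limma-voom on recovered reads, and the tests without control 2 and OSU-2S 4 or with a covariate for them were chosen only after results were seen. No paired analysis was possible because the control libraries carry the numbers 1 to 3 and the OSU-2S libraries 4 to 6. Size factors of the DESeq2 kind are already in the deposited values, and the DESeq2 Wald test was not run. Limma-voom on the recovered reads gave 1702 higher and 1549 lower genes, among them 1661 of the 1680 and 1512 of the 1519, and ended the call of 0 named genes and 0 lists. In every setting run, 0 genes changed from higher to lower or back. Total scaling, no filter, the CPM filter, limma-voom, both pseudocounts, quantile normalisation and the GC restriction gave 1475 to 1697 higher and 1397 to 1612 lower genes. Higher and lower genes numbered 847 and 547 at an adjusted p under 0.01, 726 and 242 at an absolute log2 change of at least 1, and 2597 and 2526 after GC and length correction. They numbered 3061 and 3674 without control 2 and OSU-2S 4, and 3230 and 3820 with a covariate for that pair, a split drawn from the data. Leaving out 1 library gave 954 to 1797 higher and 569 to 1967 lower genes.

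The MYC log2 fold change was -0.32 with no filter (adjusted p = 0.0831, more genes tested) and -0.35 to -0.28 without 1 library, and the CDKN1A log2 fold change was 0.46 to 0.61. Of 130 named genes that passed, 89 passed without each library in turn and 41 did not, with fewer samples in each fit. In 130 of the 132 fits that ended a call, the log2 change lay within 1 SE of that from all 6 libraries. With 3 libraries per group this share was nearly fixed in advance and does not measure stability. Named genes lost calls in 5 cases with total scaling, 9 with no filter, 7 with limma-voom on the deposited values, 4 with quantile normalisation, 1 with GC correction (RPS27L) and 1 without control 2 and OSU-2S 4 (S100A9). NUSAP1 and DEGS1 were lost under total scaling, limma-voom and quantile normalisation, for which the cause was not tested.

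With an estimated correlation, 14 of 15 lists no longer passed: adjusted p was 0.0608 for G1/S, 0.0685 for interferon-stimulated genes, 0.113 for autophagy, 0.131 for ATF4 and for NF-kB, 0.150 for immediate early genes and for histones, 0.20 for ribosome biogenesis and for NRF2, 0.215 for CDK inhibitors, 0.282 for G2/M and for heat shock, 0.305 for lysosome and 0.423 for primary granules. For autophagy and CDK inhibitors the estimated correlation was -0.0515 and -0.0615, below the preset 0.01. A higher correlation thus does not account for the loss of these lists. The degrees of freedom changed too, since the test with an estimated correlation takes them from the 6 libraries and not from the genes. That raises small p-values at any correlation. For the other lists that no longer passed, whose estimates lay above 0.01, the effects of correlation and of degrees of freedom were not separated. Fry, which does not compare a list with other genes, called 9 more lists: MYC network (adjusted p = 0.0317), monocyte (0.00102), myeloid transcription factors (0.00195), LXR (0.00102), BCL2 (0.00670), MHC class II (0.0467), hypoxia (0.00557), T cell (0.00730) and stromal (0.0140). The CDK inhibitor list gave 0.0515 after GC correction and 0.0243 to 0.0509 without 1 library. At the preset correlation, mitochondrial mRNAs gave 0.0113 with no filter and 0.0245 to 0.187 without 1 library. Ribosomal protein genes gave 0.00516 to 0.918, and turned to lower without OSU-2S 4 (adjusted p = 0.00728). The cause of these 3 was not tested. Depth limits genes such as CCL4 and NR4A3, with 3 implied reads over the controls. Low means in a group also limit genes such as S100A9, FPR2, ABCG1, GDF15, EGR2, NUPR1, BCL2A1 and S1PR2.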

Other observations

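Among the tests here, those of control 2 and OSU-2S 4, of the share of cycling cells, and of GC content and scaling for the cholesterol genes were chosen only after the result was seen, as were the gene families.

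Genes were also grouped by the stem of their symbol, giving 203 families with at least 8 tested protein-coding members, and 18 passed with the preset correlation of camera and 0 with an estimated one (adjusted p of at least 0.732). With the degrees of freedom of 6 libraries and an adjustment over 203 families, the test with an estimated correlation had little power. Its adjusted p-values therefore say little about any single family. KLF genes, which encode zinc finger transcription factors, rose in 5 of 14 cases and fell in 0 (adjusted p = 8.36e-05, and adjusted p = 0.732 with an estimated correlation). KLF6 (log2 2.79 ± 0.17), KLF7 (1.33 ± 0.19), KLF11 (0.96 ± 0.17) and KLF4 (0.78 ± 0.16) rose with KLF2, of which KLF4 lost its call without control 3 (adjusted p = 0.0513). Genes with the stem IL, most of them interleukins and their receptors, rose in 12 of 31 cases and fell in 0, led by IL4I1 (3.64 ± 0.16), which encodes an amino acid oxidase, with the receptor gene IL2RA (2.13 ± 0.17) among them (adjusted p = 0.0228, and adjusted p = 0.732 with an estimated correlation). Mitochondrial ribosomal proteins of the large subunit fell in 10 of 46 and of the small subunit in 6 of 29 cases, with 0 higher (medians -0.31 and -0.32; adjusted p = 0.000101 and 0.000834, and adjusted p = 0.780 and 0.769 with an estimated correlation). Nucleoporin genes fell in 8 of 19 cases (median -0.38, adjusted p = 0.000101, and adjusted p = 0.732 with an estimated correlation). RNA polymerase subunit genes fell in 9 of 30 cases, among them POLR3G (-1.06 ± 0.17) and POLR1A (-0.57 ± 0.10) (median -0.34, adjusted p = 0.00282, and adjusted p = 0.732 with an estimated correlation). No family median named here changed sign with quantile normalisation, and total scaling moves all genes almost alike and could not change one.

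Genes on the cholesterol list rose while the efflux genes ABCA1 and ABCG1 fell. ABCG1 was low, at means of 12.9 in control and 3.35 in OSU-2S, and its call ended in 4 fits without 1 library. GC content and length were argued against, since the median of the 24 cholesterol genes was 2.80 after correction and 2.70 before it. Scaling moves all genes of a library alike and so cannot set 1 list apart from the other genes. The list median lay 2.71 above the median of all tested genes. The size factors already hold that median near 0, so this distance repeats the list median and is no separate test. A candidate explanation is higher activity of SREBP, the transcription factor that responds to low sterol in the endoplasmic reticulum: of 13 tested SREBP genes outside the list, 11 rose and 0 fell, while PMVK (-0.26 ± 0.14) and ELOVL6 (0.48 ± 0.21) did not pass, with a median of 1.99 (camera p = 3.92e-16, and p = 0.00692 with an estimated correlation), led by FADS2 (3.01 ± 0.11), FADS1 (2.80 ± 0.12) and ACSS2 (2.78 ± 0.11). Whether OSU-2S acts on SREBP directly was not tested.

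G1/S genes fell more than G2/M genes. The gap between the list means, OSU-2S minus control, was -0.76 (SD within groups 0.0907). GC content and length are argued against, since the gap was -0.81 after correction (SD 0.0433). A smaller share of cycling cells and a delay before S phase may each fit this pattern and cannot be told apart. No value here measures cell cycle phase or how far each list follows the share of cycling cells.

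Control 2 and OSU-2S 4 departed from the means of their groups together, with deviations that correlated at 0.448 across all tested genes, which are not independent replicates. The rank correlation of the deviation with GC content was 0.69 in control 2 and 0.49 in OSU-2S 4, and -0.58 to -0.25 in the other 4 libraries. Deviations from a group mean cancel within the group, so the negative values of the other libraries are no separate observation. Over genes with a GC value the correlation of the 2 libraries was 0.507 before and 0.310 after GC and length correction, so GC and length may account for part of it and cannot be told apart from other causes, because the value fell between the bounds set for either outcome. Stromal cells as the shared cause are argued against: the 10 stromal genes summed to 2637 normalised reads in control 2 and 184 in OSU-2S 4, between the 138 and 192 of OSU-2S 5 and 6. The excess of OSU-2S 4 over the other OSU-2S libraries was thus 0.00733 of that of control 2, while its departure was 1.03 times as large. Stromal cells in control 2 alone stay open. A shared handling batch was not tested, because the labels give none.

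Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many genes as the real split, which was the real split itself with 3199 genes, and the highest of the others gave 0. That is too few splits for a share under 0.05.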
